A study of Lactobacillus delbrueckii subsp. bulgaricus
Saccharomyces cerevisiae and Saccharomyces cerevisiae with 6 samples.

How the data were processed

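RNA from 6 chemostat cultures was measured, 3 with yeast and Lb. bulgaricus and 3 with yeast alone, and groups were taken from the sample titles. Per the labels' protocols, 200 ng of total RNA per array was amplified and labelled from poly(A) tails with the Affymetrix 3' IVT Express Kit, without the poly-A spike controls, after quick quenching in liquid nitrogen and phenol/chloroform extraction. Per the labels' protocols, carry-over of bacterial RNA was judged negligible by the authors on a Bioanalyzer. The deposited values are linear probe set intensities, made with GCOS 1.2 per the submitters' processing notes. The probe summary, scaling target and filters are not given in the sources used here. The mean signal of each array after trimming 2% of probe sets at each end was 150.1 on 6 arrays, as scaling to a common target gives, so that a change in total mRNA per cell cannot be seen. No count depth applies to arrays, and the number of arrays limits the precision. The 15 poly-A control probe sets reached a signal of at most 6.1.

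Gene names were taken from the annotation table given for the array, which can hold old symbols. Of 9335 probe sets, 6504 carried 1 symbol, 328 several and 2443 none, and 60 were controls. Probe sets with several symbols or none were left out of the gene test and named no gene. The 5656 genes were each represented by the probe set with the highest mean signal, and 315 genes had more than 1. Signals below the 15th percentile of gene probe sets (11.9) were set to it and log2 was taken, with no further scaling, and 332 genes at this floor on all arrays were not tested. A gene at the floor on all arrays of a group has only a bound, and its fold is given as at least that value against the floor. Of 710 fixed members of the lists given by name, 645 were tested, and no table of older names was used. Genomic positions were not used here.

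The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on mean signal, two-sided), with Benjamini-Hochberg adjustment over 5324 genes and a threshold of 0.05. Fold changes are co-culture over monoculture. Of 45 gene lists fixed from textbook knowledge before the data were examined, 43 had at least 4 tested members and were tested with limma's camera (preset correlation 0.01), adjusted over the lists. The lists of histones and of flocculation genes had 2 tested members each and were not tested. Members were also adjusted over the list alone. The named genes were those past the threshold, up to 10 in each direction, up to 4 members of each passing list and 2 of other lists with the smallest p, and a fixed panel of 20 genes. FRE4, the single lower member of the iron list when adjusted over the list alone, falls outside this rule and was named after its values were seen. Control probe sets were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

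The gene and list tests were tested on simulated data, in 20 simulations of the comparison with 200 changed genes among 5324. At the adjusted threshold, 79.0% of genes changed by a log2 of 1 were recovered, 99.2% at 1.5 and 100% at 2, with 4.8% false calls. These rates hold for 200 changed genes and can be lower where fewer change, since the adjustment is then stricter. In the real data 11 genes passed, and ADE17 did not at a log2 fold change of 2.09 (limma adjusted p = 0.0933). Its log2 values had an SD of 0.92 in co-culture and 0.12 in monoculture. A shift of the iron list by 0.5 was found in 20 of 20 simulations, with 0 other lists called. The simulated genes varied independently of each other, each with its moderated spread, equal in both groups. The rates can therefore be too high for real genes of wider or unequal spread. They also give no measure of false list calls where genes vary together.

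The alternatives were quantile normalization, median centring, no floor, a floor at the 30th percentile, leaving out the dimmest 25% of genes, the mean of all probe sets of a gene, eBayes without a trend or with robust hyperparameters, limma treat against 1.2-fold, averaging the monoculture arrays whose names share a number, camera with an estimated correlation or on ranks, fry, and leaving out each array. Adding probe sets with several symbols, and leaving out non-coding genes, were chosen after the data were examined.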

Results

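Transcription in the yeast Saccharomyces cerevisiae was measured in anaerobic chemostats that either held yeast alone or held yeast together with Lactobacillus delbrueckii subsp. bulgaricus, a lactic acid bacterium of yoghurt. A chemostat keeps cells at a fixed growth rate by the rate at which medium is fed. The stated question was how the presence of the bacterium affects yeast. Yeast RNA from 3 co-cultures and 3 monocultures was hybridised to 6 yeast gene expression arrays, 1 per culture. All cultures ran at pH 6.0, 35 °C and a dilution rate of 0.1 per hour, and the replicates were described as independent cultures. The names of monocultures 2 and 3 share a number, and whether these were separate bioreactors is not stated, so their average was also tried. The co-cultures were fed lactose, a sugar that S. cerevisiae does not take up, whereas the labels of the monocultures give galactose as the limiting sugar. The series description instead speaks of lactose limitation with and without the bacterium. As the samples are labelled, the comparison therefore joined the presence of the bacterium with the sugar fed. Each array held 9335 probe sets, of which 6504 carried 1 gene symbol, and 5324 genes were tested. The number of arrays limited the precision, and the median half-width of the 95% confidence interval of a log2 fold change was 0.47.

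The copper transporter gene CTR3 and the iron uptake genes FIT1 and SIT1 were at higher levels in co-culture, and the sulphate permease gene SUL1 was at a lower level. Of these, only CTR3 passed in every fit with an array left out, as did STL1 and SUF1, given below. As groups, iron regulon genes and purine and one-carbon genes were higher in a test that presets the correlation between genes. Genes of anaerobic cell wall and sterol uptake, and genes of gluconeogenesis and two-carbon use, were lower in that test. All of these group calls were lost when the correlation was estimated. In limma's test with Benjamini-Hochberg adjustment, 11 genes passed an adjusted p of 0.05, 6 higher and 5 lower in co-culture, all by at least 2-fold. The 6 that rose were CTR3 for copper uptake, STL1 for glycerol uptake, FIT1 and SIT1 for uptake of siderophore-bound iron, EEB1 for ethyl ester synthesis, and FMP23. The 5 that fell were SUL1, PHM8, the transcriptional repressor gene XBP1, and the tRNA genes SUF1 and SUF6. The genes of galactose use did not differ detectably.

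CTR3 rose from a signal of 53.4 ± 8.68 in monoculture to 244 ± 47.6 in co-culture (SD, n = 3 each), a 4.55-fold difference (limma adjusted p = 0.0042). STL1 was at the detection floor on all 3 monoculture arrays and at 51.6 ± 8.23 in co-culture (SD, n = 3), at least 4.30-fold higher (limma adjusted p = 0.00263). SIT1, a siderophore transporter gene, rose 2.49-fold, from 299 ± 45.6 to 748 ± 137 (SD, n = 3 each, limma adjusted p = 0.0209). FIT1, which encodes a cell wall protein that retains siderophores, rose 2.89-fold from 24.8 ± 2.61 to 72.5 ± 16.4 (limma adjusted p = 0.0335). EEB1 rose 2.75-fold and FMP23 2.67-fold, each with a limma adjusted p of 0.0209.

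SUF1 fell from 116 ± 5.61 to 21.0 ± 6.59 (SD, n = 3 each), 5.75-fold lower in co-culture (limma adjusted p = 0.0042). SUF6 was 4.45-fold lower, and the probe sets of both tRNA genes are of a type shared within gene families and so open to cross-hybridisation. SUL1 fell from 54.9 ± 7.39 to 18.3 ± 3.70 (SD, n = 3 each), 3.02-fold lower (limma adjusted p = 0.0209). XBP1 was at the floor on all 3 co-culture arrays and at least 2.12-fold lower there, against 25.3 ± 2.29 in monoculture (SD, n = 3). PHM8 was at the floor on 2 of the 3 co-culture arrays and 2.35-fold lower by the fit. CTR3, STL1 and SUF1 passed in each of the 6 fits that left out 1 array, and the other 8 genes did not. The number of genes past the threshold was 3 without co-culture 1, 6 without co-culture 2, 4 without co-culture 3, 13 without monoculture 1, 5 without monoculture 2 and 3 without monoculture 3. It was 2 with a floor at the 30th percentile, 4 without the dimmest 25% of genes, 3 in limma's treat test against 1.2-fold, and 3 when monocultures 2 and 3 were averaged. Of the called genes, the dim filter left only CTR3, EEB1, SIT1 and SUF1 in the test, and all of these passed. With the floor at the 30th percentile, CTR3 and SUF1 passed, SUF1 with a log2 fold change of −1.68 against −2.52 as reported. FMP23 had a log2 fold change of 0.36 there, STL1 0.49, FIT1 0.97, SUL1 −0.59 and SUF6 −1.26, and PHM8 and XBP1 were not tested. There EEB1 and SIT1 had log2 fold changes of 1.46 and 1.32 as before, each with an adjusted p of 0.0805.

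**Figure D1:**
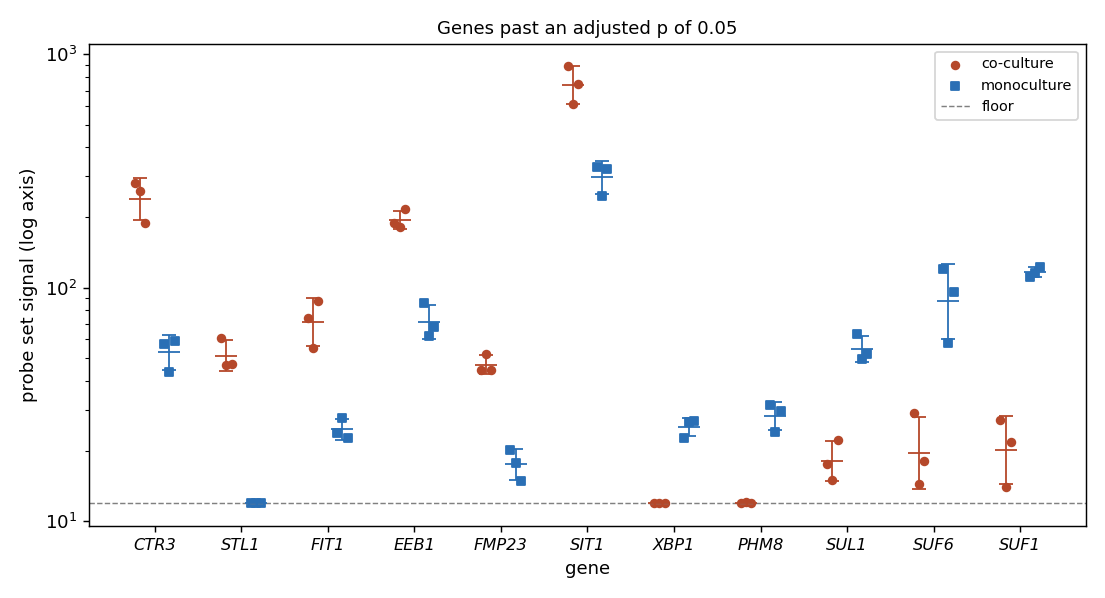
Probe set signal on each array (log axis) for the 11 genes past an adjusted p of 0.05, with co-culture as circles and monoculture as squares (n = 3 each). Horizontal marks and bars give the mean and SD of log2 values, and the dashed line is the floor of 11.9, at which STL1 lay in monoculture and XBP1 in co-culture.

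Of 43 gene lists fixed before the data were examined, 16 passed in limma's camera test with a preset correlation of 0.01, 7 higher and 9 lower in co-culture. None of the 16 passed when the correlation between genes was estimated from the data, and 5 had an unadjusted p under 0.05 in that camera test. In the 9 other ways to divide the 6 arrays into 3 and 3, each mixing arrays of both groups, the same camera test passed between 1 and 14 lists. The limma fry test, which asks whether the genes of a list move one way on balance, passed 5 lists, namely the iron regulon, the purine list, the weak acid, the glycerol and the copper lists.

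The iron regulon, the Aft1 and Aft2 targets that serve iron uptake and use, rose as a group, with a median log2 fold change of 0.70 and 25 of 26 members positive (camera adjusted p = 7.67e-16). The call was lost at adjusted p = 0.242 with an estimated correlation. Over all genes tested, 2 members passed, FIT1 and SIT1. When adjusted over the list alone, 17 members were higher and 1, FRE4, was lower in co-culture. HMX1, the haem oxygenase gene, had a log2 fold change of 1.31 ± 0.23 (SE), and the siderophore transporter gene ARN1 1.54 ± 0.30. FET3, the multicopper oxidase gene of high-affinity iron uptake, had a signal of 905 ± 309 in co-culture and 291 ± 139 in monoculture (SD, n = 3 each), a log2 fold change of 1.73 ± 0.39 (SE). None of these passed over all genes, with limma adjusted p of 0.0779, 0.136 and 0.216. FIT2, whose probe sets are open to cross-hybridisation with FIT3, had a log2 fold change of 0.70 ± 0.24.

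Genes for proteins that hold iron-sulphur clusters or haem fell as a group (17 members, median −0.29, 13 negative, camera adjusted p = 0.00281), a call lost at adjusted p = 0.338 with an estimated correlation. The median was −0.19 without co-culture 1 and −0.17 without monoculture 1 or monoculture 2. None passed over all genes, and 1 was lower when adjusted over the list alone, GLT1 for glutamate synthase (log2 fold change −0.78 ± 0.17, SE). The cytochrome c peroxidase gene CCP1 had −0.79 ± 0.29 (−0.44 without co-culture 1) and LEU1 of leucine synthesis −0.48 ± 0.20. The peroxisomal catalase gene CTA1 was at the floor on all 3 co-culture arrays. The TCA cycle list, which shares ACO1 and SDH2 with it, fell too (15 members, median −0.23, 13 negative, camera adjusted p = 0.00291). That call was lost at adjusted p = 0.406 with an estimated correlation and at 0.0642 without monoculture 2, and the median was −0.14 without co-culture 1. No TCA cycle gene passed over all genes or when adjusted over the list alone, and SDH1 had the smallest p, with a log2 fold change of −0.67 ± 0.20 (−0.44 without co-culture 1).

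The copper list rose in the camera test (7 members, median 0.21, 4 positive, adjusted p = 0.02), a call lost at adjusted p = 0.338 with an estimated correlation, 0.278 on ranks, 0.0536 without the dimmest 25% of genes and 0.0685 without monoculture 1. The median was −0.00462 without co-culture 1, 0.46 without co-culture 2, 0.56 without the dimmest genes, 0.38 with a floor at the 30th percentile and 0.59 without non-coding genes. CTR3 passed over all genes. When adjusted over the list alone, 3 members were higher and 1 lower in co-culture. The 3 were CTR3, the second copper transporter gene CTR1 (198 ± 4.65 against 89.3 ± 21.4, SD, n = 3 each) and the metalloreductase gene FRE1, also an iron regulon member. The lower one was CRS5, which encodes a copper-binding metallothionein (311 ± 26.4 against 460 ± 49.5, SD, n = 3 each).

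Purine and one-carbon genes rose as a group (17 members, median 0.72, 14 positive, camera adjusted p = 4.77e-09). The call was lost at adjusted p = 0.242 with an estimated correlation. No member passed over all genes, and 11 were higher when adjusted over the list alone. ADE17, for the last steps of inosine monophosphate synthesis, had a signal of 167 ± 101 in co-culture and 34.7 ± 2.84 in monoculture (SD, n = 3 each, limma adjusted p = 0.0933). The log2 fold change was 0.86 ± 0.17 (SE) for ADE13, 0.90 ± 0.20 for ADE1 and 1.02 ± 0.23 for GCV1, a glycine cleavage gene. ADE4, the gene of the first step of the pathway, had 0.53 ± 0.21.

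The glycerol and osmotic response list rose in the camera test (9 members, median 0.17, 6 positive, adjusted p = 0.0196), lost at adjusted p = 0.338 with an estimated correlation. It was also lost on ranks (adjusted p = 0.255), with a floor at the 30th percentile (0.157), without the dimmest 25% of genes (0.741), without co-culture 2 (0.0779) and without monoculture 1 (0.218), and the median was 0.11 without co-culture 1 and 0.10 without co-culture 2. STL1 passed over all genes, and 3 members were higher when adjusted over the list alone, the others being GRE2 (log2 fold change 0.69 ± 0.18, SE) and GPP2 (0.63 ± 0.20). Phospholipid synthesis genes rose as a group (17 members, median 0.17, 15 positive, adjusted p = 0.0192), with an adjusted p = 0.406 with an estimated correlation. That call also ended without co-culture 3 (adjusted p = 0.112) and without monoculture 3 (0.144), and the median was 0.32 without monoculture 1 and 0.04 without monoculture 3. None of its members passed over all genes or when adjusted over the list alone, and the ethanolamine phosphotransferase gene EPT1 had the smallest p (log2 fold change 0.90 ± 0.34, or 0.54 without monoculture 2).

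Ribosome biogenesis genes rose as a group (51 members, median 0.23, 41 positive, camera adjusted p = 0.00191), and this was lost at adjusted p = 0.691 with an estimated correlation. None passed over all genes or when adjusted over the list alone, with DBP8 at 0.61 ± 0.23 and RLP7 at 0.79 ± 0.34 (log2 fold change, SE, or 0.38 and 0.51 without co-culture 1). Without co-culture 1, the array that stood apart on the first principal component, the median was 0.04 (adjusted p = 0.875), and without monoculture 3 it was 0.14 (0.111). Without co-culture 3 the median was 0.39. Mitochondrial ribosomal protein genes rose as well (54 members, median 0.19, 40 positive, adjusted p = 0.0169), with an adjusted p = 0.43 with an estimated correlation. Without co-culture 3 and monoculture 2 in turn, their adjusted p was 0.259 and 0.0762, with a median of 0.12 without monoculture 2. None passed over all genes or when adjusted over the list alone, and RSM25 had the smallest p (0.81 ± 0.21).

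Genes for anaerobic cell wall proteins and sterol uptake fell as a group (11 members, median −0.66, 10 negative, camera adjusted p = 2.12e-04), lost at adjusted p = 0.344 with an estimated correlation and with a median of −0.34 without co-culture 1. No member passed over all genes, and 2 were lower when adjusted over the list alone, both sterol transporters of the plasma membrane. These were PDR11 (169 ± 9.65 against 282 ± 34.6) and AUS1 (385 ± 95.5 against 667 ± 117, SD, n = 3 each). The mannoprotein genes TIR3 and TIR4 had log2 fold changes of −0.81 ± 0.27 and −0.87 ± 0.31 (SE), and without co-culture 1 TIR4 had −0.54. The seripauperins, a family of near-identical genes open to cross-hybridisation, fell in the camera test (10 members, median −0.36, 9 negative, adjusted p = 0.00291). Their call was lost at adjusted p = 0.43 with an estimated correlation and at 0.0582 without co-culture 1, where the median was −0.20, against −0.61 without co-culture 2. None of them passed over all genes or when adjusted over the list alone, with PAU7 at −1.17 ± 0.35. The cell wall integrity list fell (19 members, median −0.17, 13 negative, adjusted p = 0.00281), with an adjusted p = 0.406 with an estimated correlation. The median was −0.30 without co-culture 2, −0.09 without co-culture 3, −0.28 without monoculture 3 and −0.06 with a floor at the 30th percentile. Its single member past the threshold when adjusted over the list alone was PRM5 (−0.94 ± 0.22), and none passed over all genes.

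Genes of gluconeogenesis and two-carbon use fell as a group (14 members, median −0.34, 12 negative, camera adjusted p = 2.18e-04), lost at adjusted p = 0.338 with an estimated correlation and with a median of −0.56 with a floor at the 30th percentile. None passed over all genes, and 1 was lower when adjusted over the list alone. That was ADH2, the ethanol-oxidising alcohol dehydrogenase gene, at 28.1 ± 6.36 against 70.5 ± 10.9 in monoculture (SD, n = 3 each). The acetyl-CoA synthetase gene ACS1 had a log2 fold change of −0.96 ± 0.33 (SE), and the acetate permease gene ADY2 was at the floor on all 3 co-culture arrays. Trehalose and glycogen genes fell as well (16 members, median −0.36, 15 negative, adjusted p = 2.18e-04). Their call was lost at adjusted p = 0.43 with an estimated correlation and at 0.129 without co-culture 1, where the median was −0.11. None of them passed over all genes or when adjusted over the list alone, with the glycogen debranching gene GDB1 at −0.66 ± 0.23 (−0.41 without co-culture 1).

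The weak acid response list of Haa1 targets fell (10 members, median −0.22, 9 negative, camera adjusted p = 0.00291), lost at adjusted p = 0.338 with an estimated correlation, 0.0878 with a floor at the 30th percentile and 0.0981 without the dimmest 25% of genes, and its median was −0.38 without a floor. PHM8 passed over all genes and was the single member lower when adjusted over the list alone, while STP3 had a log2 fold change of −0.48 ± 0.16 (SE). The phosphate regulon fell (11 members, median −0.28, 8 negative, adjusted p = 0.0167), with an adjusted p = 0.406 with an estimated correlation. The call also ended without co-culture 2 (adjusted p = 0.0771) and without co-culture 3 (0.0536). No phosphate gene passed over all genes. When adjusted over the list alone, the phosphate transporter gene PHO84 was lower (76.0 ± 19.6 against 216 ± 94.7, SD, n = 3 each) and PHM6 was higher (78.0 ± 23.9 against 42.8 ± 4.29).

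**Figure D2:**
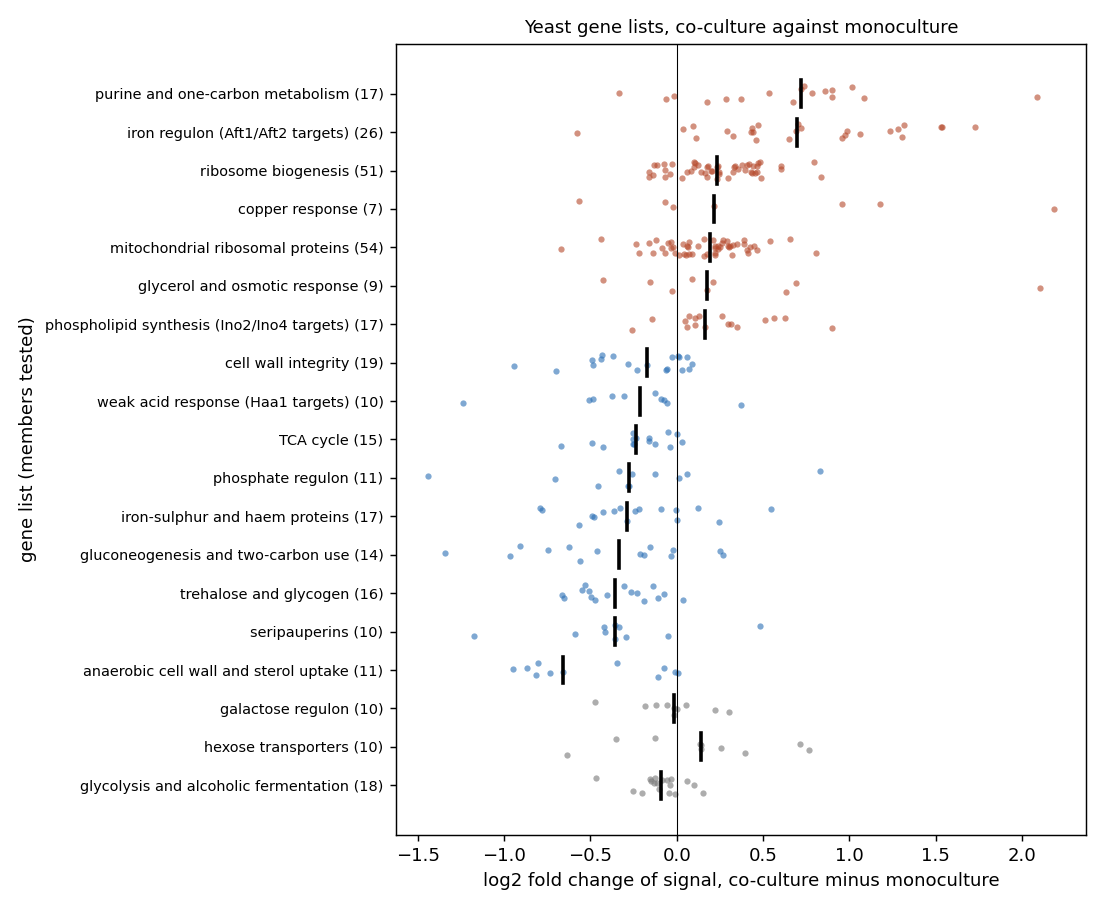
Log2 fold change of each tested member (points) and the median (black bar) for the 16 lists that passed in camera, 7 higher (red) and 9 lower (blue) in co-culture, and for 3 lists that did not pass (grey). The iron regulon and the purine list have medians of 0.70 and 0.72, and the galactose regulon −0.01.

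The other 27 lists did not pass, with camera adjusted p from 0.0573 for the respiratory chain to 0.836. The camera direction was lower for pyrimidine synthesis against a median of 0.06, and the mean and median differed in sign for multidrug resistance (0.01 and −0.04) and aromatic amino acid catabolism (0.01 and −0.03). The galactose regulon had 0 of 10 members past the threshold over all genes or adjusted over the list alone (limma, 0 also at an unadjusted p of 0.05), with a median of −0.01 and an adjusted p of 0.815. GAL1, the galactokinase gene, had a signal of 1709 ± 244 in co-culture and 1644 ± 214 in monoculture (SD, n = 3 each), with a 95% confidence interval of the log2 fold change from −0.36 to 0.47. The log2 fold change was −0.12 ± 0.25 (SE) for the galactose permease gene GAL2, −0.27 ± 0.20 for GAL4 and −0.05 ± 0.20 for GAL80. Among hexose transporters, 0 of 10 passed over all genes or adjusted over the list alone (limma, 3 at an unadjusted p of 0.05), with HXT10 at 0.76 ± 0.24 and HXT5 at 0.71 ± 0.24. HXT7, open to cross-hybridisation with HXT6, had 0.14 ± 0.15.

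Lactate genes had a median of 0.42 over 5 members (camera adjusted p = 0.0765). None passed over all genes, and 1 was higher when adjusted over the list alone, the lactate dehydrogenase gene DLD1 (1251 ± 154 against 840 ± 139, SD, n = 3 each). CYB2, for lactate oxidation, had a log2 fold change of 0.96 ± 0.35 (SE, or 0.56 without monoculture 3) and the lactate permease gene JEN1 −0.40 ± 0.17. In the general stress list XBP1 passed over all genes. When adjusted over that list alone it was lower, and HSP12, for a small heat shock protein, was higher at 0.78 ± 0.20. In the sulphur list SUL1 alone passed, over all genes and adjusted over the list alone. The glycolysis list had no member past either threshold, with PDC1 at −0.12 ± 0.24 and ADH1 at −0.11 ± 0.25. Other genes fixed beforehand had log2 fold changes of 0.10 ± 0.20 (SUC2), 0.32 ± 0.25 (NCE103), 0.15 ± 0.20 (OLE1), 0.24 ± 0.16 (ERG11) and −0.04 ± 0.20 (ACT1), and FDH1 was not tested.

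Across genes, the log2 values of arrays of the same group correlated at r = 0.961 to 0.979, and those of different groups at 0.943 to 0.980. Co-culture 1 stood apart on the first principal component, which held 38.3% of the variance, with a score of −23.3 against −4.31 to 17.9 for the other 5 arrays. Monocultures 2 and 3 lay at its other end (17.9 and 12.9), and monoculture 1 (−0.27) lay near co-cultures 2 and 3. On the second component (27.0%), monoculture 3 had 20.5 against −11.0 to 9.05 for the others. Monoculture 1 had a mean r of 0.969 with its own group and 0.972 with the co-cultures. The 3' over 5' signal ratio of the actin control differed by 0.19 on the log2 scale (exact permutation p = 0.5, two-sided). For the controls YER148W and YER022W it differed by 0.16 and −0.06 (exact permutation p = 0.6 and 0.9). In co-culture and monoculture the mean ratio was 1.57 and 1.37 for actin, 2.56 and 2.28 for YER148W, and 8.43 and 8.80 for YER022W. The mean signal of the 18S rRNA probe sets was lower in co-culture by a log2 difference of −0.87 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows), and that of the 25S rRNA probe sets by −0.68 (p = 0.2), or −0.39 without co-culture 2. Adjusted over 6 control measures, the p was 0.6 for both. All 10 rRNA probe sets had lower means in co-culture, with a median log2 difference of −0.66, beside the gene groups given above. At an unadjusted p of 0.05, 439 genes (8.25%) passed, 227 higher and 212 lower. The groups of 3 values did not overlap for 707 genes, 13.3% against 10% by chance for a single gene. Genes vary together across the 6 arrays, so the share over genes can differ from 10% without a group difference.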

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

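The number of arrays limits the precision, and the gene count depended on the floor and on the arrays used. The 11 genes past the threshold, all changed at least 2-fold, became 2 genes by both counts with a floor at the 30th percentile. There STL1, FMP23 and SUL1 move closer to the floor by construction, but EEB1 and SIT1 do not and also lost their calls (adjusted p 0.0805). There were 4 by both counts without the dimmest 25% of genes, a filter that took STL1, FIT1, FMP23, SUL1, SUF6, PHM8 and XBP1 out of the test. With the monoculture arrays of 1 name number averaged, which leaves fewer samples, there were 3 by both counts. limma treat against 1.2-fold, a stricter test, called 3. Leaving out 1 array gave 3 to 13 genes by both counts, 3 without co-culture 1, 6 without co-culture 2, 4 without co-culture 3, 13 without monoculture 1, 5 without monoculture 2 and 3 without monoculture 3. The other settings called 9 to 16 genes, the 9 without non-coding genes, an alternative chosen after seeing the data, as was adding probe sets with several symbols (12). The 16 lists became 0 with an estimated correlation (smallest adjusted p 0.242) and 5 with fry, and 14 to 19 in the other settings, 15 to 17 of these without 1 array. The iron and purine lists passed in each setting but the estimated correlation, with medians of 0.65 to 0.88 and 0.68 to 0.73, and in all 6 leave-one-out fits. The mean correlation within groups moved from 0.971 to 0.956 without the dimmest 25%, which removes the lowest signals by construction. No paired analysis was possible because the labels give the groups no shared replicate numbers.

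Of 124 genes chosen by the naming rule that did not pass, 57 moved by over 1.5 times in log2 fold change with 1 array left out, 23 of them at 0.5 or more as reported. Directions turned only for genes and lists that did not pass as reported, and the cause was not tested. With 1 array left out, the log2 fold change ranged from −0.056 to 0.159 for GAL1, −0.295 to 0.0933 for GAL2, −0.242 to 0.059 for GAL80, −0.0192 to 0.304 for SUC2, −0.012 to 0.232 for OLE1, −0.303 to 0.0865 for PDC1, −0.335 to 0.0425 for ADH1 and −0.185 to 0.103 for ACT1. With the monoculture arrays averaged, ADH1 was at 4.3e-05 and ACT1 at 0.0338. The camera direction turned in some fits for lists whose medians with 1 array left out ranged from −0.158 to 0.074 (galactose regulon), −0.126 to 0.0167 (sucrose and maltose use), −0.102 to 0.0182 (protein folding), −0.092 to 0.00999 (aromatic amino acid catabolism), −0.0752 to 0.114 (cytosolic ribosomal proteins), 0.0612 to 0.216 (daughter cell separation), −0.172 to 0.0344 (multidrug resistance), −0.221 to −0.0155 (glycolysis), −0.155 to −0.0213 (oxidative stress) and −0.031 to 0.157 (pyrimidine synthesis). The copper list kept its direction, although its median was −0.00462 to 0.455 with 1 array left out. The pyrimidine list turned also with the 30th percentile floor (0.0614), without the dimmest genes (0.0642) and on ranks (0.0614).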

Other observations

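Some genes outside the fixed lists, chosen after their values were seen, did not pass the threshold. CIN5, a stress transcription factor gene, had a log2 fold change of 1.36 ± 0.24 (SE), and AQR1, for a multidrug transporter, was at the floor on all 3 monoculture arrays and at least 2.29-fold higher in co-culture. ATO3, of the ammonium transport family, had −1.04 ± 0.18. These 3 had a limma adjusted p of 0.0779. CHA1, the serine deaminase gene, was at 70.3 ± 15.3 in co-culture and 22.5 ± 20.1 in monoculture (SD, n = 3 each, limma adjusted p = 0.289).

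Among 1238 probe sets with several symbols or none, 3 passed an adjusted p of 0.05 in limma, 3 lower and 0 higher in co-culture. The one with symbols covers the mitochondrial gene COB and its intron BI4 and had a log2 fold change of −1.44 ± 0.15 (SE), with 2 of 3 co-culture arrays at the floor. The other 2, without a symbol, were at the floor on all 3 co-culture arrays. All 15 mitochondrially encoded probe sets above the floor on at least 1 array had lower means in co-culture, with a median of −0.33. Many of them lay near the floor, and several were of the same gene, COX1 or COB. The brightest, for OLI1 and COX1, had log2 fold changes of −0.31 and −0.28, and both were lowest on co-culture 2 (signals of 870 and 678). Without co-culture 2, 14 were lower and 1 higher, with a median of −0.21, and without monoculture 3, 12 were lower and 1 higher, with −0.24. The median was −0.49 without monoculture 1 and −0.58 without co-culture 3. Of 58 Ty element probe sets, 34 were higher in co-culture, with a median of 0.11. The probe set shared by HXT13, HXT15, HXT16 and HXT17 had a log2 fold change of 0.93 ± 0.24 (limma adjusted p = 0.295).

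The tests of non-coding RNA, of the copper genes, of genes of like signal and of other divisions of the arrays for the gene counts were chosen only after the results were seen. The higher iron regulon was weighed against 3 technical explanations. Leaving out each array left its median at 0.59 or more, which argues against 1 array as the source. Across 5 settings of scaling, floor and dim filter the median stayed at 0.65 or more. A general addition of bacterial signal is argued against by 827 probe sets below the floor in monoculture, whose median gain in co-culture was −0.0333 signal units, and by 1067 genes of like monoculture signal with a median log2 fold change of 0.03 (quartiles −0.16 to 0.19). With 1 array left out, that gain was −0.1 to −0.0167 and that fold change −0.0046 to 0.0425. Binding of bacterial RNA to single probe sets was not tested, and a lower iron supply to yeast in co-culture may be a candidate explanation, which these data cannot separate from the sugar fed. The galactose regulon did not differ detectably (median log2 fold change −0.01), but this leaves other effects of the feed open.

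The higher purine and one-carbon genes were weighed in the same way. Without each array in turn the median stayed at 0.53 or more, and across the 5 settings at 0.68 or more. Both argue against 1 array or the scaling as the source. A lower purine supply in the co-culture medium may be an explanation, but no test here bears on it, and the sugar fed stays open.

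The lower rRNA control signal was weighed against poorer labelling of all RNA without a poly(A) tail. The 102 non-coding genes had a median log2 fold change of −0.0314 (−0.0975 without co-culture 1 and 0.0143 without co-culture 2). The 65 of them above the floor on each array had 0.10 (quartiles −0.22 to 0.34, median 0.01 without co-culture 1, 0.03 without monoculture 1, and 0.17 without co-culture 2 or monoculture 3), against −0.66 for the rRNA probe sets. This argues against a loss common to all such RNA, but not against one limited to part of it. SUF1 and SUF6 fell, and the mitochondrial transcripts, which lack poly(A) tails in yeast, were lower too (median −0.33 over 15 probe sets, −0.21 without co-culture 2 and −0.58 without co-culture 3). Many of those 15 probe sets lay near the floor, and several were of the same gene. The brightest, for OLI1 and COX1, lay within the range of the monocultures on co-cultures 1 and 3 and below it on co-culture 2. Bacterial rRNA in the same 200 ng would dilute yeast mRNA and yeast rRNA alike, and the arrays share a common mean signal. Dilution alone would therefore not lower the rRNA signal against the genes, and the authors judged carry-over of bacterial RNA negligible. Another composition of the yeast RNA in co-culture may lower the rRNA signal and was not tested.

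The iron-using list had a median of −0.29 over the 11 members not shared with the TCA cycle or respiratory chain lists, 7 of them lower. That median was −0.19 without co-culture 1, −0.14 without monoculture 1, −0.17 without monoculture 2 and −0.46 without monoculture 3. In the copper list, 5 targets of the low-copper activator Mac1, with log2 fold changes from −0.02 to 2.19, had a median of 0.96 and the storage and detoxification genes CRS5 and SOD1 −0.31 (exact permutation p = 0.143, two-sided, over the 7 genes).

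The 10 divisions of the 6 arrays into 3 and 3, the real one included, are too few for a share under 0.05. The real division gave 11 genes and the others at most 0, also at a 2-fold minimum, so that 1 of 10 gave as many. Each other division mixes arrays of both groups, so a true group difference widens its spread and partly stays in its contrast. The counts of genes and lists in those divisions therefore give no rate of false calls. Cytosolic ribosomal proteins passed in 7 of the 9 other divisions, and glycolysis and protein folding in 4 each. None of these lists passed in the real division, so a group difference does not account for their calls. Hexose transporters, which also did not pass there, passed in 0 others. Camera with the preset correlation can therefore pass lists without a detectable group difference, and its p can be too small where genes vary together. By limma, the real division had 439 genes at an unadjusted p of 0.05 and the others up to 481. For lists the real division gave 16 and the highest other 14, so that 1 of 10 gave as many. Of the 16 lists, 6 had their smallest p in the real division, and 1, the copper list, passed in no other. The iron list passed in 6 and the purine list in 3 of the 9 other divisions, with p down to 1.93e-10 and 6.92e-06 against 1.78e-17 and 2.22e-10 in the real one. The trehalose and glycogen list passed in 8 of them, with p down to 1.42e-05 against 2.54e-05. Ribosome biogenesis had a smaller p in 6 other divisions, down to 2.52e-15 against 2.66e-04.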
